A study of Mus musculus with 6 samples.

How the data were processed

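Single-cell RNA sequencing was carried out on mouse embryonic stem cells (ESC) of 2 genotypes at 3 stages. The labels name the genotypes parental and Oct1_cKO, written cKO here for conditional knockout. Oct1 is the POU-domain transcription factor encoded by Pou2f1. The stages were undifferentiated ESC, day 3 and day 6 of a differentiation towards mesoderm, and each of the 6 groups held 1 library. Per the labels' protocols, ESC were plated on 0.1% gelatin and kept for 2 days in N2B27 medium with Bmp4, a growth factor of the TGF-beta family. They were then kept for 4 days in DMEM-based medium with Rspo3, which enhances Wnt signalling, and LDN-193189, an inhibitor of BMP receptors. Cells were harvested with trypsin, and libraries were prepared with the 10x Genomics Single Cell 5′ kit, so a UMI (unique molecular identifier) counts a tag from the 5′ end of a transcript.

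Per the submitters' processing notes, the authors processed the reads with Cell Ranger on the mm10 genome, and per the file headers the software version was 3.1.0. The deposited values were UMI counts per gene and cell barcode for 31053 genes, and every value was a whole number. No cell annotation was used. Gene positions came from the GENCODE annotation of the same genome build, matched by Ensembl identifier for 30934 of the 31053 genes.

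A barcode was kept as a cell when it held UMIs of at least 1000 genes and at most 10% of its UMIs came from mitochondrial genes. Scrublet, run within each library through scanpy 1.11.5, removed 38 further barcodes as doublets. It marked 0 parental and 1 cKO barcode at day 6, which is too few to count as a working doublet filter at that stage, so doublets remain open there. Of 11046 barcodes, 7058 were kept. The matrices were processed in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

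UMIs were summed over the kept cells of a library and scaled to the library total as CPM (counts per 1e6). CPM carry exact Poisson 95% intervals. Log2 ratios of 2 libraries carry exact conditional binomial 95% intervals. A library with no UMI of a gene was set to a floor of 3 counts, and the ratio is then a bound. Genes were counted as different when the ratio was at least 2-fold and the higher library held at least 20 CPM. Data for day 6 were simulated with counting error alone, without variation between libraries. In them, all 50 genes with a 4-fold rise and all 50 with a 4-fold fall were recovered, and 0% of 5543 unchanged genes were called. False calls between real libraries are not measured by this. At the 2-fold limit itself, 2% of 50 genes with a 2-fold rise and 90% of 50 with a 2-fold fall were called. The median ratio of unchanged genes was −0.05, so in the simulation rises near the limit were counted less often than falls. That shift arose because the simulated changes entered the library total. In the data the median log2 ratio of all genes compared at day 6 was −0.01. The intervals held the true ratio for 95.2% of the unchanged genes.

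Genes named by size were, per stage, Pou2f1 and the up to 12 highest and 12 lowest log2 ratios among genes with at least 20 CPM in the higher library, UMIs in at least 5% of its cells and at least a 2-fold difference. A prior of 1 CPM was added for this ranking, and mitochondrial, ribosomal protein and unnamed genes were left out. From each of 40 gene lists, up to 3 members with the largest ratios were named as well. Any other gene is said to have been chosen after its values were seen. A list was summarised by the median log2 ratio of its members with at least 5 CPM in the higher library, with an order-statistic 95% interval over genes. Its percentile was taken among 10000 random lists of the same size, matched on expression in 20 bins. The lists, thresholds and naming rule were fixed before the data were examined.

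The cells of both genotypes of a stage were clustered together without batch correction. The steps used 2000 variable genes chosen within each library, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.8 (igraph 0.11.9). A cluster was named after a cell type, with the ending "-like", only when at least 3 markers fixed beforehand were detected for it and its leading genes did not go against the name. Shares of cells carry Clopper-Pearson intervals, and differences of shares carry Newcombe intervals. As a reading that does not rest on clusters, each cell was thinned to 3000 UMIs and the share of cells with UMIs of at least 2 genes of a list was taken. Cells were also given a chromosome score, with chromosomes and limits chosen after the data were seen. Each chromosome's share of a cell's UMIs was set, as a log2 ratio, against the median cKO cell of the stage. The score was the mean ratio of chromosomes 1, 6 and 8 minus that of chromosome 11. Cells above 0.25 formed the group with chromosomes 1, 6 and 8 high, and cells below the negative of that limit the group with chromosome 11 high. The groups are ranges of 1 score, a cell with all 4 chromosomes raised falls between them, and the reference centres the cKO cells on neither group. Cells needed at least 5000 UMIs in the scored genes. Alternate genes along each chromosome assigned the cells, and the other genes measured the groups.

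Alternatives were TMM factors (edgeR 4.0.16) and median-of-ratios size factors (DESeq2 1.42.0) in R 4.3.3, totals without mitochondrial and ribosomal protein genes, and equal weight per cell. Others were expression minimums of 5 and 50 CPM, other filters of barcodes, doublets kept, other clustering settings and other depths of thinning. Subsets of cells (without the fibroblast-like cluster, at least 20000 UMIs, neither chromosome group, without neural-like clusters) were chosen after seeing the data. With 1 library per group no test within a stage was possible. A fit across the 6 libraries with stage and genotype as terms was not run, and no p-value was computed. Figures were drawn with matplotlib 3.10.9.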

Results

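Mouse ESC of a parental and a cKO genotype were profiled by droplet single-cell RNA sequencing before differentiation and at days 3 and 6 of differentiation towards mesoderm. Each of the 6 groups held 1 library. By the title of the series, the comparison of genotypes asks how Oct1, with the Smad transcription factors that carry BMP and TGF-beta signals, acts in the specification of mesoderm. The libraries held between 41665721 and 85102600 UMIs. At the ESC stage 1387 parental and 519 cKO cells were kept, with medians of 51708 and 70107 UMIs per cell. At day 3 there were 941 and 1016 cells with medians of 82483 and 78916 UMIs, and at day 6 there were 1546 and 1649 cells with medians of 36219 and 30911 UMIs. With no replicates, the differences below describe pairs of libraries. The 95% intervals of CPM, ratios and shares cover counting error only, and those of list and chromosome medians are taken over genes. The sample titles of the ESC libraries start with 17418 and those of days 3 and 6 with 17425, so the step from ESC to day 3 also crosses that prefix, whose meaning the labels do not state.

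Pou2f1 (ENSMUSG00000026565, mm10 chromosome 1, 165865154 to 166002678, minus strand), the gene of Oct1, was lower in the cKO library at each stage. It measured 30.2 CPM (29.0 to 31.4) in parental and 21.9 CPM (20.4 to 23.4) in cKO ESC, a log2 ratio of −0.47 (−0.58 to −0.35). At day 3 it measured 28.3 and 12.7 CPM, a ratio of −1.16 (−1.26 to −1.05). At day 6 it measured 30.9 and 16.1 CPM, a ratio of −0.94 (−1.05 to −0.84). A 5′ tag outside the deleted part of a gene is counted whether or not the part is present. The labels do not say which part was deleted, so these values do not measure how complete the deletion was. Its paralog Pou2f3 was higher in cKO, at 3.55 and 21.5 CPM in ESC and at 1.62 and 14.2 CPM at day 3. Both libraries lay below 1 CPM for Pou2f3 at day 6.

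The differentiation of the parental cells sets the scale for the genotype comparison. From ESC to day 3, genes of naive pluripotency, the state of ESC in culture, fell in the parental libraries for 14 of 15 measured members (median log2 ratio −3.29; −3.89 to −1.93). Tfcp2l1 went from 221 to 8.02 CPM and Klf4 from 209 to 9.78 CPM. Of the genes of the primed epiblast, the later pluripotent state, 9 of 12 were at least 2-fold higher, with a median of 2.50 (−0.40 to 4.44). Fgf5 went from 0.311 to 12.6 CPM and Pou3f1 from 7.26 to 189 CPM. Of the list of neuromesodermal progenitors, the axial stem cells of spinal cord and trunk mesoderm, 6 of 8 members were higher, with a median of 2.23 (−0.93 to 5.81). Among them T, a regulator of the primitive streak, went from 4.85 to 42.3 CPM. The cKO libraries moved by −3.77 for the naive list (13 of 15 lower), 2.35 for the primed list (9 of 12 higher) and 3.48 for the neuromesodermal list (5 of 7 higher). Of all genes compared, 302 were at least 2-fold higher and 490 lower at day 3 than in ESC in parental, and 392 and 637 in cKO. Part of the parental fall belongs to fibroblast genes, for which 9 of 9 list members were lower at day 3, with a median of −4.04.

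From day 3 to day 6, both genotypes lost pluripotency genes and gained genes of presomitic mesoderm and somites, the segmented mesoderm that forms muscle and skeleton. The general pluripotency list had 10 of 12 members lower in parental (median −2.61) and 11 of 12 in cKO (−2.94). The somite list rose in both, with 8 of 9 members higher in parental (median 4.39; 2.20 to 5.82) and 6 of 7 in cKO (4.15; 0.69 to 11.71). Genes of epithelial-to-mesenchymal transition were higher for 12 of 12 members in parental (2.52) and 11 of 12 in cKO (2.45). The neural list parted the genotypes. In parental, 14 of 17 members were higher at day 6 (median 3.39; 1.44 to 5.64), including Hes5, a target of Notch signalling in neural progenitors, from 0.611 to 88.4 CPM. In cKO, 1 of 7 members was higher and 3 were lower (median −0.78; −6.82 to 2.27). A member counts only with at least 5 CPM in the higher library of its own genotype, so these 2 medians rest on different sets of genes. The cKO list of surface ectoderm and epithelium rose with a median of 1.81 (0.08 to 5.44; 7 of 11 higher), and Krt18, a keratin of simple epithelia, went from 51.5 to 2179 CPM. In parental, 4 of 10 members were higher and 2 lower (median 0.53; −1.10 to 3.99). In all, 839 genes were at least 2-fold higher and 289 lower at day 6 in parental, against 1220 and 426 in cKO.

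In ESC, the genotypes differed in few genes of pluripotency and in many genes of fibroblasts. The naive list had a median log2 ratio of cKO over parental of 0.11 (−0.07 to 0.28), with 0 of 15 members at least 2-fold higher and 1 lower. That member, Dppa3, measured 13.7 CPM in parental and 3.08 CPM in cKO. The list of feeder fibroblasts, cells often used to support ESC, was lower in cKO for 9 of 9 members, with a median of −4.39 (−5.37 to −2.15) below all 10000 random lists. Its members include Lox, an enzyme that crosslinks collagen (20.8 and 0.133 CPM; −7.30, −8.92 to −6.07), Col1a2, a chain of type I collagen (50.4 and 1.22 CPM), and Acta2, smooth muscle actin (116.5 and 3.29 CPM). Mgp, an inhibitor of calcification, measured 500.2 and 13.2 CPM, and Grem1, a secreted BMP antagonist, 48.6 and 0.848 CPM. S100a4, Bgn, Igfbp7, Fbln2, Timp2 and Ltbp2 were also among the 12 lowest genes. A cluster of 123 parental and 3 cKO cells, led by these genes and called fibroblast-like, made up 8.87% (7.42 to 10.5) of the parental and 0.578% (0.119 to 1.68) of the cKO library. Crlf2 (ENSMUSG00000033467, chromosome 5, 109554709 to 109558993), a cytokine receptor chain, lay outside that group: it was detected in 69.4% of parental and 2.70% of cKO cells, at 42.8 and 0.636 CPM (−6.07; −6.72 to −5.50).

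Higher in the cKO ESC were Foxd1 (ENSMUSG00000078302, chromosome 13, 98354242 to 98359305), a forkhead factor, from 20.7 to 137 CPM (2.73; 2.65 to 2.81), Pou2f3 (2.60; 2.40 to 2.80) and Ebf1, a transcription factor of B cells and mesenchyme, from 24.4 to 79.7 CPM (1.71; 1.63 to 1.79). Others were Crym, Ak4, an adenylate kinase, Saa3, an acute-phase protein, Ptges, a prostaglandin synthase, Fam25c and Rras, a small GTPase. Peg10, an imprinted gene of retroviral origin, measured 49.4 and 130.4 CPM. The Y-linked Uty measured 10.7 and 30.2 CPM and Ddx3y 48.1 and 125.9 CPM. The list of hypoxia and glycolysis had a median of 0.37 (−0.01 to 0.56), above all random lists, with 0 of 13 members at least 2-fold different. Its member Eno1, a glycolytic enzyme, measured 526 and 893 CPM. Of the surface ectoderm list 2 of 8 members were higher, Krt8 (105.5 and 216 CPM) and Tfap2a (4.17 and 8.70 CPM), with a median of 0.27 (−0.02 to 1.06). An epithelium-like cluster led by Krt18, Krt8, Krt7 and the imprinted H19 held 5.05% of parental and 22.0% of cKO cells, a difference of 16.9 points (13.3 to 20.8). In all, 46 genes were at least 2-fold higher and 69 lower among 5350. Without the fibroblast-like cluster, a subset chosen after seeing the data, the counts were 52 and 17. With at least 2000 genes and at most 5% mitochondrial UMIs per cell (453 parental and 85 cKO cells) they were 124 and 44.

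At day 3 the 2 libraries were closest (Spearman correlation of CPM across genes 0.977), and Ccnd2, Cdx2, Fgf8 and Hoxb1 were among the genes lower in cKO. The neuromesodermal list had a median of −0.59 (−1.60 to 0.83), with 3 of 8 members at least 2-fold lower and the median below all random lists. With TMM or median-of-ratios factors 2 of 8 were lower. The 3 were Cdx2, a caudal homeobox factor of posterior identity, from 26.7 to 8.81 CPM (−1.60; −1.73 to −1.48), Fgf8, a growth factor of the primitive streak, from 49.5 to 18.0 CPM (−1.46; −1.54 to −1.37), and Cdx1, from 20.6 to 10.2 CPM (−1.01; −1.13 to −0.89). Of the 3 measured Hox genes of paralog groups 1 to 4, which pattern the hindbrain and trunk, Hoxb1 (10.98 and 2.95 CPM) and Hoxb2 (9.85 and 4.42 CPM) were lower. The cell cycle gene Ccnd2 (ENSMUSG00000000184, chromosome 6, 127125162 to 127152193) had the lowest ratio of the stage, from 101.1 to 31.5 CPM (−1.68; −1.75 to −1.62). Lpl, Palld, Sgk1, Mylpf, Gdf3, Mt2 and Cyct were also more than 2-fold lower. Of these, Ccnd2 and Gdf3 lie on chromosome 6 and Lpl, Palld and Mt2 on chromosome 8. The Wnt response list had a median of −0.28 (−1.01 to −0.07; 2 of 10 lower) and the list of FGF and ERK response −0.24 (−0.83 to −0.06; 1 of 11 lower). The Smad genes had a median of −0.36 over 5 members, 0 of them 2-fold different.

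Higher in cKO at day 3 were Adgrb2, an adhesion receptor, from 3.25 to 21.1 CPM (2.70; 2.50 to 2.89), Rras (18.2 and 68.8 CPM), Ebf1 (6.91 and 21.2 CPM), Nefm, a neurofilament chain, Smagp, Gadd45b, Ctgf, a target of YAP and TGF-beta signals, and Mirg, an imprinted RNA. The Y-linked Ddx3y, Eif2s3y and Uty were higher as well, with Ddx3y at 26.7 and 76.7 CPM. A cluster of day 3 cells led by Ccnd2, Cdx2, Hoxb1 and Hoxb2 held 295 parental cells and 1 cKO cell. It stayed unnamed, and a cluster mostly of 1 library may be that library, not a type. Of its parental cells with a chromosome score, 98.6% had chromosomes 1, 6 and 8 high. Other unnamed clusters, with T among their leading genes, held mostly cKO cells. That led by Adgrb2 and Enpp2 held 37 parental and 276 cKO cells, and that led by histone genes such as Hist1h1b held 11 and 175. Under 4 other settings a day 3 cluster was named neuromesodermal-like, with more parental cells each time: 270 of 687 parental and 1 of 797 cKO cells with the stricter filter of barcodes, 59 and 1 with 1000 variable genes, 73 and 17 with 4000, and 40 and 14 at resolution 1.2. A naive-like cluster held 11.9% of parental and 0.787% of cKO cells, and 99.1% of its scored parental cells had those chromosomes high too. The reading without clusters did not show a lower share in cKO: at least 2 naive genes were seen in 44.3% of parental and 53.01% of cKO cells thinned to 3000 UMIs (8.75 points; 4.28 to 13.2). With at least 3 genes the difference was 0.93 points (−2.75 to 4.59), and at 0.5 of the depth −0.22 points (−4.16 to 3.70). In cells of neither chromosome group the neuromesodermal median was −0.33 (−1.12 to 0.77), with 1 of 8 members lower.

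In all, 13 genes were at least 2-fold higher and 14 lower at day 3 among 5151, so 48.1% of the different genes were higher. With TMM factors 59.3% were higher, with median-of-ratios size factors 62.1%, and with equal weight per cell 35.7%. Median-of-ratios factors moved the median log2 ratio of all genes at day 3 by 0.12, from −0.05 to 0.07, and the list medians of that stage are to be read relative to that shift. Across the 3 stages, 2 genes were at least 2-fold higher in cKO each time, Uty and Ddx3y, and 1 was lower each time, Ccnd2.

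At day 6 the libraries lay furthest apart (Spearman correlation of CPM across genes 0.887), with the neural program lower and epithelial genes higher in cKO. Of 16 measured neural genes 15 were at least 2-fold lower, with a median of −4.08 (−4.55 to −2.69) below all random lists. Pax6 (ENSMUSG00000027168, chromosome 2, 105668900 to 105697364), a regulator of neural progenitors, measured 38.04 CPM in parental and 0.352 CPM in cKO (−6.75; −7.40 to −6.18). Sox1, an early neural gene, measured 29.8 and 0.881 CPM (−5.08; −5.47 to −4.71). Crabp1, which binds retinoic acid, measured 739 and 24.9 CPM (−4.89; −4.96 to −4.82), and Tubb3, the tubulin of neurons, 144 and 8.16 CPM (−4.15; −4.27 to −4.02). Pantr1, Mir124-2hg, Sfrp2, Pou3f2, Sox3, Pou3f3 and Nhlh2 were also among the 12 lowest genes. Of the Notch and somite clock list 5 of 7 members were lower (median −1.91; −4.50 to 0.28), among them Hes5 (88.4 and 3.92 CPM), Lfng (6.01 and 0.866 CPM) and Dll1 (12.95 and 1.98 CPM). Sox2, shared by neural and pluripotent cells, measured 111 and 11.2 CPM.

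Genes of the surface ectoderm and epithelium list were higher in cKO for 10 of 11 members, with a median of 1.497 (1.26 to 1.85) above all random lists. Tfap2a, a regulator of surface ectoderm, measured 2.90 and 16.6 CPM (2.52; 2.30 to 2.74). Krt7 measured 67.9 and 245 CPM (1.85; 1.81 to 1.90), and Grhl2, a regulator of epithelial junctions, 4.69 and 16.9 CPM (1.85; 1.67 to 2.03). Krt8, Krt18, Cdh1 and Epcam rose from 746 to 1863, from 910 to 2179, from 34.0 to 95.8 and from 188 to 476 CPM. These 4 genes, and Tcf15 and Hoxb4 below, were chosen after their values were seen. Wnt6 (ENSMUSG00000033227, chromosome 1, 74771892 to 74785322), a ligand of surface ectoderm, measured 62.3 and 511.5 CPM (3.04; 2.99 to 3.08), Cd9, a tetraspanin, 221 and 1225 CPM (2.47; 2.45 to 2.50), and Perp, a component of desmosomes, 51.2 and 282 CPM. Tchh, Wnt10a, Npnt, Tgm1, an enzyme of cornified epithelium, Ahnak2, Gnai1, Mal, Neat1 and the hormone precursor Pomc completed the 12 highest. Pomc was detected in 20.1% of parental and 14.7% of cKO cells while its CPM went from 8.83 to 76.6, and a cluster it leads, with T, Shh and Fgf8, held 21 parental and 69 cKO cells.

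Lists of mesodermal genes went in both directions at day 6. The somite list had a median of −0.44 (−0.80 to −0.14), with 1 of 9 members at least 2-fold lower and the median at percentile 4.30 of random lists. That member was Uncx, of the posterior half-somite, at 13.3 and 4.75 CPM. With equal weight per cell the median of the list was −0.0773. Tcf15 measured 79.7 and 56.4 CPM and Meox1 67.5 and 40.2 CPM, both regulators of somites. Of the list of dermomyotome and muscle, 3 of 5 members were lower (median −1.31). Pax3 measured 51.0 and 20.6 CPM and Pax7 10.7 and 0.484 CPM, and both also mark dorsal neural tube. Of the genes of epithelial-to-mesenchymal transition 5 of 12 were lower (median −0.59; −1.18 to 0.33). The streak list had 4 of 7 members higher (median 1.02; −2.47 to 2.11), with T at 4.68 and 17.3 CPM and Sp5, a Wnt target, at 12.5 and 53.9 CPM. Hba-x and Hbb-bh1, embryonic globins, were seen in parental cells alone, at 177.5 and 50.6 CPM. Against the floor of 3 counts over the cKO library the log2 ratio of Hba-x was −11.98, a bound. The BMP and TGF-beta list had a median of 0.29 (−0.27 to 0.67; 1 of 12 higher, 2 lower) and the Smad genes 0.07 (−1.03 to 0.50; 1 of 6 lower). That member, Smad1, lies on chromosome 8 and measured 31.7 and 15.5 CPM.

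Over all cells of day 6, Hox genes were lower in cKO. Of paralog groups 1 to 4, 7 of 9 members were at least 2-fold lower (median −1.78; −2.41 to −0.64), including Hoxa2 (36.7 and 6.91 CPM) and Hoxb4 (59.5 and 17.4 CPM). Of groups 5 to 9, which pattern the trunk, 10 of 13 were lower (median −1.47; −2.38 to −0.77), including Hoxb9 (54.3 and 6.59 CPM; −3.04, −3.19 to −2.90), Hoxb8 (19.96 and 3.07 CPM) and Hoxc8 (19.8 and 3.82 CPM). Both medians lay below all random lists. A neural-like cluster of 137 parental and 15 cKO cells was led by Hoxb9, Hoxc8 and Hoxc9. Without the neural-like clusters, a subset chosen after seeing the data, the medians were −0.77 for groups 1 to 4, with 1 of 7 members lower, and −1.11 for groups 5 to 9, with 8 of 11 lower. Within the somite-like cluster the median of groups 1 to 4 was not below 0, at 0.32 (−0.16 to 1.01; 2 of 10 higher, 0 lower). Groups 5 to 9 had a median of −0.47 (−0.86 to 0.32; 1 of 13 higher, 1 lower). Both intervals include 0. Of the scored cells of that cluster, 84.9% in parental and 11.3% in cKO had chromosome 11 high.

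In all, 314 genes were at least 2-fold higher and 254 lower at day 6 among 6172, and 55.3% of the different genes were higher. Without the neural-like clusters the counts were 150 and 109. Across 6484 genes, the difference between genotypes at day 6 had a Spearman correlation of 0.119 (0.0945 to 0.143) with the parental change from day 3 to day 6, with no parental day 6 cell in both ratios. With minimums of 5 and 50 CPM it was 0.0159 and 0.216. Genes are not independent replicates. Of 968 genes at least 2-fold higher at day 6 in that part of the parental cells, 135 were lower and 121 higher in cKO.

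**Figure D1:**
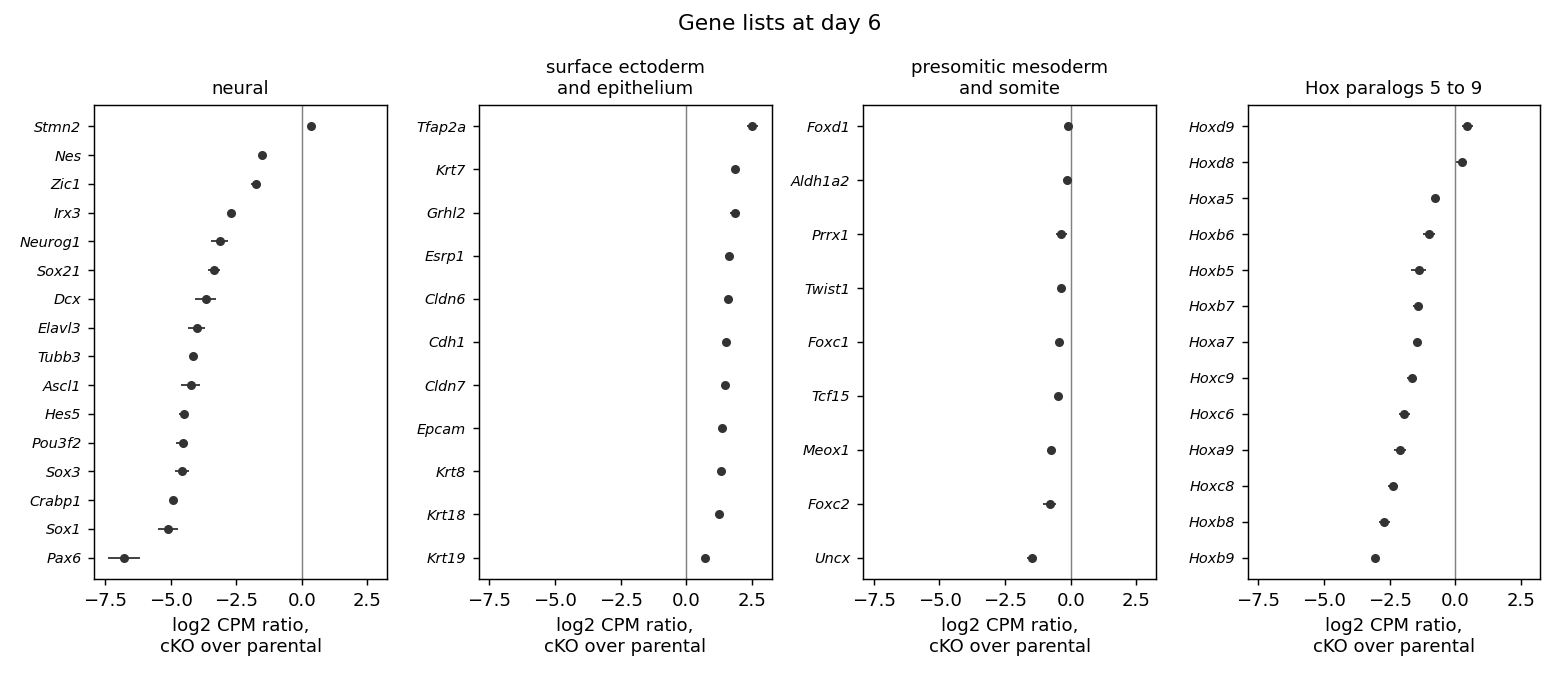
Points give the log2 ratio of CPM in cKO over parental at day 6 for the members of 4 gene lists with at least 5 CPM in the higher library, with 95% intervals of counting error. The vertical line marks equal levels. Of the neural genes 15 of 16 lie at least 2-fold below that line, and of the surface ectoderm and epithelium genes 10 of 11 lie at least 2-fold above it.

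The cell classes of day 6 differed along the same lines. Neural-like cells (clusters led by Fabp7 and Sfrp2, by Tubb3 and Elavl3, and by Hoxb9) made up 38.4% (593 of 1546) of parental and 1.70% (28 of 1649) of cKO cells, a difference of −36.7 points (−39.2 to −34.2). Epithelium-like cells made up 12.9% of parental and 40.3% of cKO cells (27.5 points; 24.5 to 30.3). Their cluster led by Cd9 held 44 parental and 357 cKO cells, and the one led by Cited1 and Krt8 held 155 and 308. Somite-like cells, a cluster with Tcf15, Meox1 and Twist1 among its leading genes, made up 16.1% and 12.7% (−3.43 points; −5.88 to −0.998). General pluripotency genes were lower for 6 of 12 members and higher for 1 (median −0.996; −2.39 to −0.24), and naive-like cells made up 6.34% and 0.667%. Blood-like cells numbered 8 in parental, and 0 of 1649 cKO cells allow a share of up to 0.223%. All 7 of the blood-like cells with a chromosome score had chromosomes 1, 6 and 8 high, and 0 of the 183 parental cells in neither chromosome group were blood-like, so this difference is not separate from that of the chromosomes. Unnamed cells made up 25.4% and 43.8%, mostly of 2 clusters with medians of 4958 and 4722 UMIs per cell, and 31.1% of parental and 42.8% of cKO cells had under 20000 UMIs. Among cells with at least 20000 UMIs, neural-like cells made up 47.7% and 2.12%, epithelium-like cells 17.7% and 66.6%, and somite-like cells 22.3% and 20.02%. The somite-like difference changed sign with the clustering: at resolution 1.2 it was 7.04 points.

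Shares of cells with at least 2 genes of a list, at 3000 UMIs per cell, need no clusters. Neural genes marked 45.8% of parental and 5.76% of cKO cells at day 6 (−40.0 points; −42.8 to −37.2), and epithelial genes 31.2% and 76.1% (44.9 points; 41.6 to 48.0). Somite genes marked 14.0% and 13.1% (−0.900 points; −3.38 to 1.58), a difference not detectable at this depth. Naive genes marked 5.32% and 5.42% (0.104 points; −1.54 to 1.74). They marked 54.2% (52 of 96) and 90.9% (10 of 11) of naive-like cells, 8.12% and 7.37% of epithelium-like cells and 0 of 249 and 0 of 208 somite-like cells, so 52 of the 77 marked parental cells were naive-like and 10 of the 81 marked cKO cells. For these shares, 98 parental and 155 cKO cells with fewer UMIs were left out. As background, neural genes marked 14.9% of parental and 7.21% of cKO somite-like cells, whose median depths were 54190 and 48828 UMIs, and 7.61% and 3.01% (1.85 to 4.61) of epithelium-like cells. The cKO share of 5.76% (4.63 to 7.06) lay between the cKO values of these classes. Of the neural-like cells themselves, neural genes marked 91.9% in parental and 52.0% (31.3 to 72.2; 13 of 25) in cKO. Epithelial genes marked 3.45% of parental and 24.0% of cKO neural-like cells (median depths 38172 and 40452 UMIs), and 15.3% and 23.6% of somite-like cells. Without thinning, the differences were −37.5 points for neural, 36.3 points for epithelial and −7.74 points for somite genes. Naive genes then marked 30.5% of parental and 42.5% of cKO cells, so their difference at day 6 depended on the setting.

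**Figure D2:**
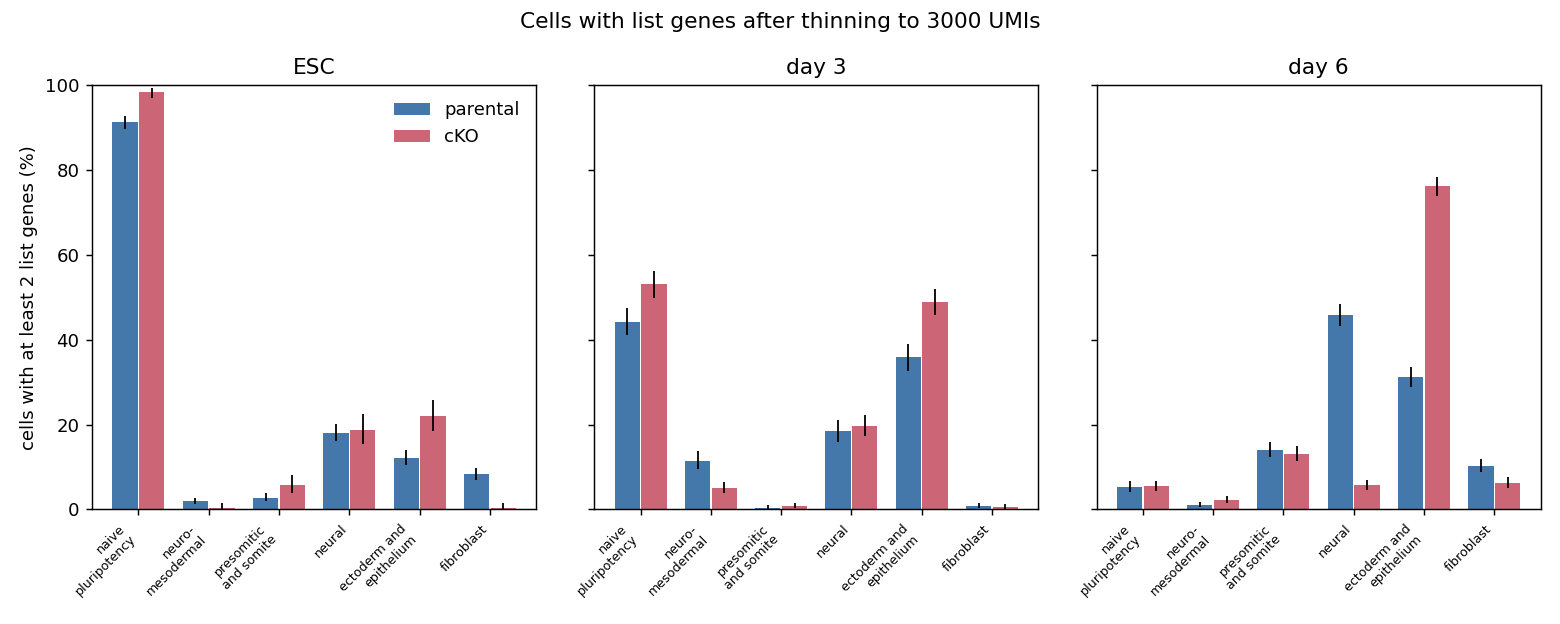
Bars give the percentage of cells with UMIs of at least 2 genes of a list after each cell was thinned to 3000 UMIs, for parental (blue) and cKO (red) libraries at the 3 stages, with Clopper-Pearson 95% intervals. At day 6 the neural bars stand at 45.8% and 5.76% and the ectoderm and epithelium bars at 31.2% and 76.1%.

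Whole chromosomes also differed between the genotypes, and several of the genes above lie on them. At day 3 the median log2 ratio of cKO over parental was −0.29 for chromosome 1, −0.29 for chromosome 6, −0.31 for chromosome 8 and −0.20 for chromosome 11. In ESC these chromosomes had medians of −0.10, −0.14, −0.15 and −0.28, and at day 6 of −0.08, −0.17, −0.20 and −0.31. When the genes of a chromosome were split by position into 6 parts, all 6 parts of each of the 4 had medians below 0 at each stage. The same held for chromosome 16 in ESC and at day 3, with a median of −0.10 at both stages, and for chromosome 3 at day 3, with −0.06. The medians of chromosomes 3 and 16 at day 3 are smaller than the shift of 0.12 given above, and that of chromosome 1 at day 6 is smaller than the 0.09 by which TMM factors moved all genes there. Pou2f1 itself lies on chromosome 1, and in cells of neither chromosome group it measured 28.8 and 22.0 CPM in ESC, 24.7 and 12.6 CPM at day 3, and 37.5 and 16.7 CPM at day 6. Of the scored parental cells, those with chromosomes 1, 6 and 8 high made up 27.7% in ESC, 53.9% at day 3 and 35.96% at day 6, those with chromosome 11 high 41.99%, 32.9% and 48.0%, and cells of neither group 30.3%, 13.1% and 16.0%. Of the cKO cells, the reference of the score, 94.1%, 94.97% and 89.5% were in neither group. Scores from the assigning and the other genes correlated across parental cells at 0.914, 0.970 and 0.966, and 8.14%, 2.31% and 4.82% of those cells lay within 0.05 of a limit. In cKO the correlations were lower, 0.435, 0.653 and 0.698, and 5.03%, 3.49% and 8.40% (88 of 1048) of cells lay that near a limit.

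The chromosome groups of parental cells differed in other genes. The summed CPM of 3 Y-linked genes was 24.7, 21.7 and 29.1 in cells with chromosomes 1, 6 and 8 high and 120.2, 116 and 105 in cells with chromosome 11 high. In cells of neither group the sum was 100.4, 90.3 and 86.8 CPM in parental and 225, 165 and 263 CPM in cKO. The gap between the shifted parental groups lay mostly in 2 of the genes. At day 3 Ddx3y measured 9.12 and 46.8 CPM and Eif2s3y 3.4 and 58.7 CPM in these groups. Uty measured 9.25 and 10.1 CPM there, and 8.54 and 11.3 CPM in ESC. Meg3, an imprinted RNA, measured 15.7 CPM in parental day 3 cells with chromosomes 1, 6 and 8 high and 822 CPM in those with chromosome 11 high. Meg3 and the values of Ccnd2 by group were chosen after they were seen. Ccnd2 in cells of neither group measured 98.7 CPM in parental and 9.51 CPM in cKO ESC, 78.2 and 32.1 CPM at day 3, and 297 and 48.0 CPM at day 6. At day 6, neural-like cells made up 80.2% of parental cells with chromosomes 1, 6 and 8 high, 24.3% (20.8 to 28.1; 133 of 547) of those with chromosome 11 high and 42.1% (34.8 to 49.6; 77 of 183) of those in neither group. In the cKO library neural-like cells made up 2.56% (1 of 39), 19.7% (11.2 to 30.9; 14 of 71) and 0.853% (8 of 938) of these groups. Among cells with chromosome 11 high the intervals of the 2 genotypes thus overlap, which is no test of equal shares. In cKO that group held 60.9% (14 of 23) of the scored neural-like cells but 6.78% (71 of 1048) of all scored cells. Whether the score follows the cell class there was not tested. In cells of neither group 182 genes were at least 2-fold higher and 207 lower at day 6, the neural median was −5.19 (15 of 16 lower) and 6 of 11 epithelial genes were higher. At day 3 the counts in these cells were 4 and 27, and epithelium-like cells made up 27.8% of parental and 27.6% of cKO cells. Over all day 3 cells they made up 15.6% and 27.2% (11.5 points, 7.93 to 15.1). The larger cluster of that name at day 3 (114 parental and 144 cKO cells) was named from Krt8, Krt18 and Krt19. Its leading genes included the stress response genes Ddit3, Atf5 and Trib3. In ESC of neither group the counts of genes were 32 and 167. Of these ESC, 16.8% (62 of 369) in parental were fibroblast-like against 0.233% (1 of 430) in cKO.

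**Figure D3:**
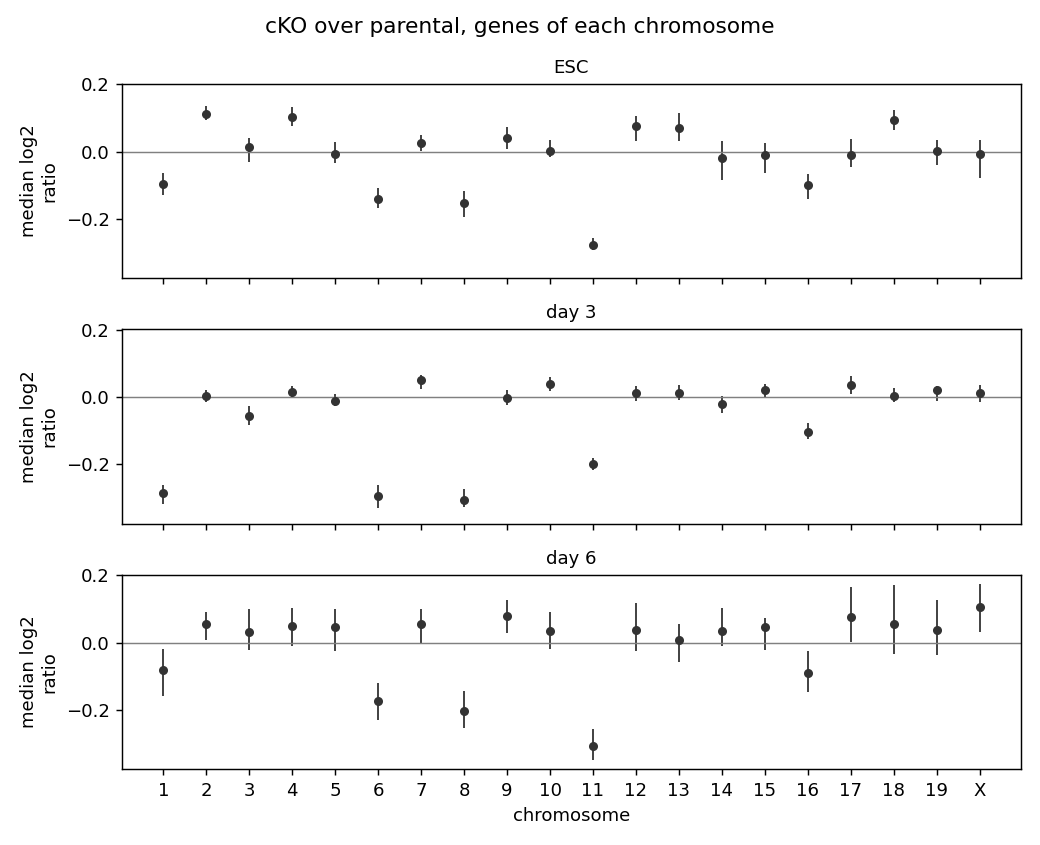
Points give the median log2 ratio of cKO over parental for the genes of each chromosome with at least 20 CPM in the higher library, with order-statistic 95% intervals over genes, at the 3 stages. Chromosomes 1, 6, 8 and 11 lie lowest at day 3, between −0.31 and −0.20.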

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

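The test on deep cells, and the subsets of cells used in all tests here, were chosen after the results were seen. Elavl3, Sox1 and Tubb3, genes of neurons and their progenitors, stood out because they moved in opposite directions in the 2 genotypes from day 3 to day 6. Their log2 changes were 1.44, 1.89 and 1.65 in parental and −1.73, −1.86 and −1.88 in cKO, so the cKO change minus the parental change was −3.17, −3.75 and −3.52. Grem1 and S100a4 moved in opposite directions from ESC to day 3, by −3.53 and −4.04 in parental and by 2.05 and 1.72 in cKO, differences of 5.58 and 5.76. The cKO changes rest on few cells: Grem1 was detected in 1.93% of them in ESC and 0.787% at day 3 and S100a4 in 1.54% and 1.08%, while 3 of 519 and 5 of 1016 cells were fibroblast-like. With 1 library per group, none of these differences was tested.

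The neural genes and neural-like cells were lower in cKO at day 6. A higher number of shallow cells in the cKO library is argued against, because among cells with at least 20000 UMIs the share of neural-like cells still differed by −45.5 points (−48.6 to −42.3). A supply of neural-like cells by the parental cells with shifted chromosomes alone is argued against as well, since 42.1% (34.8 to 49.6) of the parental cells in neither group were neural-like. Loss of Oct1 stays open. In cells of neither group the share differed by −41.2 points (−48.5 to −34.3), but in cells with chromosome 11 high it was 24.3% (20.8 to 28.1) in parental and 19.7% (11.2 to 30.9; 14 of 71) in cKO, intervals that overlap. That overlap cannot decide, because in cKO this group held 14 of 23 scored neural-like cells but 71 of all 1048. The score may thus follow the cell class there. On genes not used to assign cells, chromosome 11 in those 71 cKO cells, 14 of them neural-like, lay 0.361 (0.317 to 0.403) above cKO cells of neither group. In the parental group it lay 0.340 (0.305 to 0.368) above. Of all 1048 scored cKO cells of day 6, 88 lay within 0.05 of a limit of the score, not counted by group. Neural genes marked 91.9% of parental but 52.0% (13 of 25, 31.3 to 72.2) of cKO neural-like cells, so the class may not hold the same cells in both. This is also 1 pair of libraries. Other differences between the parental and cKO cultures stay open for the same reason, among them the Y-linked genes and Ccnd2, which differed in cells of neither group too.

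The fibroblast genes were lower in cKO ESC, and Grem1 and S100a4 follow them. Fibroblasts caught in the parental library are a candidate explanation. The summed CPM of the 9 measured list members was 428 with all cells and 9.81 without the fibroblast-like cluster, against 20.7 and 4.79 in cKO. The cluster was named from this same list, so that fall was fixed beforehand. It does not tell caught fibroblasts from parental ESC that express these genes. The median ratio of those 9 genes without the cluster was −1.96 (−3.66 to 0.09), neither near 0 nor clearly below −2, and 0 of them then reached 5 CPM, so RNA released from fibroblasts and a remaining difference cannot be told apart. An effect of Oct1 loss in the ESC themselves called for an interval below 0 and did not get it, since the upper bound was 0.086. It is not excluded, since the median was not near 0. Of the 9 genes 1 is also on the list of epithelial-to-mesenchymal transition, and the highest in parental ESC were Acta2 (116.5 CPM), S100a4 (99.0 CPM) and Col1a1 (64.8 CPM). The labels do not say whether feeder cells were used.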

How the results depend on the processing

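Each group held 1 library, so leaving out a replicate was not possible, and a fit that pairs the libraries of both genotypes by stage was not run. Where a value moved, the cause was not tested. Depth set the lowest level seen: 0 UMIs in the cKO ESC library, the one with the fewest UMIs, allowed up to 0.0978 CPM.

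A count was taken as close within 1.5 times the reported one, and a median, a difference of shares or the correlation when it lay inside the 95% interval of the reported value, or inside the range of its genes for a list too short for an interval. A sign change was counted for a reported value whose interval excluded 0.

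Of 70 counts of 2-fold genes under other choices, 49 stayed close and 21 moved. With 5 CPM there were 129 genes higher and 248 lower in ESC, 24 and 54 at day 3, and 565 and 677 at day 6. With 50 CPM there were 23 and 28, 4 and 4, and 177 and 95. Cells with at least 2000 genes and at most 5% mitochondrial UMIs (453 parental and 85 cKO) gave 124 higher and 44 lower in ESC, which turned the balance round. Among cells of neither chromosome group 167 genes were lower in ESC, 4 were higher and 27 lower at day 3, and 182 were higher at day 6. Without the fibroblast-like cluster 17 genes were lower in ESC, and without the neural-like clusters 150 were higher and 109 lower at day 6.

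Of 82 medians of the main lists 76 stayed and 6 moved, none across 0. At day 6 the neural list stood at −4.71 with the stricter filter, −5.19 in cells of neither group and −1.21 without the neural-like clusters. The surface ectoderm and epithelium list stood at 1 and 0.78 in the last 2 sets, and the somite list at −0.0773 with equal weight per cell. Among other lists 2 values crossed 0, both of the mitochondrially encoded genes: −0.11 in ESC with the stricter filter and −0.0114 at day 6 with equal weight per cell.

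Of 56 differences in the main cell classes 36 stayed, 16 moved and 4 changed sign, and 1 of 39 other class differences changed sign, that of epithelium-like cells at day 3. The somite-like difference at day 6 was 7.04 points at resolution 1.2, 0.437 with proliferation genes left out and 4.98 in cells of neither group. In those cells the naive-like difference was 0.757 at day 3 and −3.41 at day 6, and the epithelium-like difference at day 3 was −0.210. The naive-like difference at day 3 was −7.72 at resolution 1.2, −7.66 with proliferation genes left out and −8.25 with doublets kept. The neural-like difference at day 6 was −40.4 at resolution 1.2, −40.1 with 1000 and −41.3 with 4000 variable genes, −45.5 in cells with at least 20000 UMIs and −41.2 in cells of neither group. The epithelium-like difference at day 6 was 19.3 at resolution 1.2, 48.9 in cells with at least 20000 UMIs and 30.6 in cells of neither group. In ESC it was 22.3 at resolution 0.4, 12.8 with 1000 and 10.6 with 4000 variable genes, and 21.7 with proliferation genes left out. Some names were lost: at day 3 the naive-like, neural-like and epithelium-like ones at resolution 0.4 and the neural-like and fibroblast-like ones with the stricter filter, in ESC the fibroblast-like and epithelium-like ones with that filter, and at day 6 the endoderm-like one with that filter and with proliferation genes left out. A neuromesodermal-like cluster at day 3, not named in the reported setting, differed by −39.2 with the stricter filter, −6.17 with 1000 and −6.08 with 4000 variable genes, and −2.87 at resolution 1.2. Others named only in other settings were at day 6: streak-like with 4000 variable genes (12 parental and 54 cKO cells) and the stricter filter (5 and 35), and fibroblast-like with that filter (31 and 18) and with proliferation genes left out (102 and 18).

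Of the shares of thinned cells, the neural difference at day 6 was −25.35 points with at least 1 gene, −31.9 with at least 3 and −30.1 at 0.5 of the depth. The surface ectoderm and epithelium difference was 39.5 with at least 1 gene and 36.3 without thinning, and the somite difference −4.46 and −7.74. Among the other lists 8 differences changed sign. Without thinning these were neuromesodermal genes in ESC (2.18) and at day 6 (−3.80), streak genes (4.48) and proliferation genes (0.760) at day 3, and fibroblast genes at day 6 (0.774). At 0.5 of the depth, naive (−0.221) and general pluripotency genes (−2.02) did so at day 3, as did endoderm genes with at least 1 gene (−1.02). The correlation with the parental time course was 0.0159 at 5 CPM and 0.216 at 50 CPM.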

Other observations

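The test of copy number with its groups of cells, and the tests of chromosomes within neural-like cells and within single clusters, were chosen after the results were seen. Stress and cell cycle genes differed at day 6 as well. Of the p53 response list 4 of 12 members were at least 2-fold higher in cKO and 1 was lower, with a median of 0.80 (0.36 to 1.42) above all random lists. Cdkn1a, an inhibitor of the cell cycle, measured 139 CPM in parental and 373 CPM in cKO, Mdm2, the negative regulator of p53, 79.5 and 188 CPM, and Trp53inp1 35.0 and 103.5 CPM. The other higher member was Perp, given above with the epithelial genes, so the list is not separate from the larger epithelial share. Of 16 proliferation genes 15 lay below 0 and 1 was at least 2-fold lower, Top2a (405.5 and 175 CPM), with a median of −0.66 (−0.90 to −0.36). Cdkn1a and Mdm2, and the genes given within classes below, were chosen after their values were seen. The share of thinned cells with at least 2 proliferation genes was 85.8% in parental and 66.0% in cKO. Of the list of heat shock and immediate early genes, which also respond to the dissociation of cells, 5 of 12 were higher (median 0.92; 0.14 to 1.16), with Fos at 18.1 and 60.7 CPM. In cells of neither chromosome group the medians were 0.77 for p53 response, −0.63 for proliferation and 0.56 for immediate early genes.

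Within the somite-like cluster of day 6 (249 parental and 209 cKO cells), 94 genes were at least 2-fold higher and 54 lower among 5925. Of its scored cells, 84.9% (208 of 245) in parental and 11.3% (23 of 203) in cKO had chromosome 11 high. Differences within this cluster are therefore not separate from those of the chromosome groups. The somite list had a median of 0.01 (−0.42 to 0.38; 1 of 14 lower), with Tcf15 at 190.1 and 252 CPM and Meox1 at 195 and 174 CPM. Of the Wnt response list 5 of 9 members were higher (median 1.01; 0.38 to 2.13) and of the p53 list 4 of 12 (0.68; 0.50 to 1.38), with Cdkn1a at 125 and 326 CPM. Acta2 measured 2603 and 919 CPM. The surface ectoderm and epithelium list was higher there as well for 6 of 8 members (median 1.998; −0.45 to 2.86), so free RNA from other cells stays open as a source of such differences. Within the epithelium-like clusters (199 parental and 665 cKO cells, of which the parental ones came mostly from the cluster led by Cited1 and the cKO ones about evenly from both), the epithelium list had a median of 0.02 (−0.40 to 0.33). Krt8 measured 3246 and 2525 CPM there, Wnt6 274 and 710 CPM, and Cd9 860 and 1756 CPM. The p53 list had a median of 0.49 (0.07 to 0.74) there, with 0 of 12 members at least 2-fold higher and 1 lower. The proliferation list had a median of −0.49 (−0.60 to −0.29). Of the scored cells of these clusters, 60.9% (117 of 192) in parental and 4.18% (27 of 646) in cKO had chromosome 11 high.

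The genes of chromosomes 1, 6, 8 and 11 were lower together in cKO. A different mixture of cell classes as the whole cause is argued against for chromosome 11, whose genes had a median of −0.395 (−0.41 to −0.37) within the somite-like cluster at day 6. Within the epithelium-like clusters led by Cited1 and by Cd9 the median of chromosome 11 was −0.321 (−0.36 to −0.28) and −0.097 (−0.13 to −0.06). Within the neural-like cells (28 of them cKO) the median of chromosome 11 had the opposite sign, 0.146 (0.08 to 0.17). By cluster it was 0.271 (0.22 to 0.32) in that led by Fabp7 and 0.217 (0.13 to 0.30) in that led by Tubb3. In that led by Hoxb9 it was −0.024 (−0.08 to 0.02). For chromosomes 1, 6 and 8 the neural-like cells cannot decide on the mixture, since the class may not hold the same cells in both genotypes. The median of those chromosomes there was −0.293 (−0.335 to −0.271), an interval over genes that carries no error from the few cKO cells. The genotypes filled the 3 neural-like clusters differently, but the median was also below 0 within each: −0.429 (−0.47 to −0.39; 7 cKO cells) in that led by Fabp7, −0.258 (−0.320 to −0.193; 6 cKO cells) in that led by Tubb3 and −0.198 (−0.240 to −0.158; 15 cKO cells) in that led by Hoxb9. Within the somite-like cluster the median of those chromosomes was 0.03 (0.01 to 0.05) and within the epithelium-like clusters 0.02 (0.01 to 0.05), so the differences of all 4 chromosomes lay in some classes and not in others. Of the scored neural-like cells, 61.0% in parental had chromosomes 1, 6 and 8 high and 60.9% (14 of 23) in cKO had chromosome 11 high. A hypothesis is that the parental culture held cells with extra copies of chromosomes 1, 6 and 8, low in the Y-linked Ddx3y and Eif2s3y. By the same hypothesis both cultures held cells with an extra chromosome 11, far more of them in parental. On genes not used to assign cells, the high chromosomes of the parental groups lay 0.379 to 0.431 above cells of neither group in ESC and 0.343 to 0.483 at day 3, against 0.585 for 3 copies over 2, and 0.245 to 0.340 at day 6. The other chromosomes of both parental groups were to lie within 0.2 of 0, and not all did. In cells with chromosome 11 high, chromosome 16 lay 0.213, 0.248 and 0.178 above at the 3 stages, and at day 6 chromosomes 1 and 8 stood at −0.221 and −0.228. In cells with chromosomes 1, 6 and 8 high, chromosome 11 stood at −0.252 at day 6. Cells with chromosome 11 high were not particular to parental. In cKO, 37 of them at day 3 and 71 at day 6 had chromosome 11 at 0.416 (0.36 to 0.45) and 0.361 (0.32 to 0.40) over cKO cells of neither group, with chromosome 16 at −0.04 and −0.03. The 39 cKO cells of day 6 grouped as chromosomes 1, 6 and 8 high had these at 0.10, 0.06 and −0.06. The lowest value of the high chromosomes, 0.245, is under the bound of 0.3 set for this test and above the 0.2 that would argue against it. The bound of 0.3 and that of 0.2 around 0 were both missed, so expression alone leaves copy number open, as DNA was not measured here.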
